A study of Mus musculus with 5 samples.

How the data were processed

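RNA from 4 mouse medulloblastomas and 1 P5 mouse cerebellum had been hybridised to Affymetrix expression arrays. Per the labels, RNA came from a Trizol extraction for medulloblastomas 1 to 3 and the cerebellum, whereas the entry for medulloblastoma 4 names only the manufacturer's standard procedure. The deposited values are intensities, 1 per probe set and array, on a linear scale. Per the submitters' processing notes they were made with MAS5 for medulloblastomas 1, 2 and 4 and the cerebellum; no tool is stated for medulloblastoma 3. In the deposited intensities the mean of each array after removing 2% of the probe sets at each end was 500.002, for medulloblastoma 3 as well. Detection calls were not used here. The number of arrays limits the precision, and no depth applies. The ratio of 3' to 5' signal, a check of RNA integrity, was between 1.21 and 1.45 for actin and between 0.731 and 0.946 for Gapdh on the 5 arrays.

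Arrays were grouped by the tissue in their labels and numbered in the order of the records, so the number is only a name. The labels give no genotype, treatment or sex, and no age other than the P5 in the title of the cerebellum. Titles start with ken for medulloblastomas 1 and 2 and with hmk for the other 3 arrays; this prefix was treated as a possible batch. No pairing was possible with 1 cerebellum.

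The table held 45101 probe sets, of which 64 were controls. The platform annotation supplied with the table gave 1 gene symbol for 34945 probe sets and several for 932, which were not used, and 9160 others were unnamed here. Of the named probe sets, 34741 were found by Entrez gene ID in the RefSeq genes of GRCm38.p6, used for names only, and 0 symbols changed. Each of the resulting 18193 genes was represented by its probe set with the highest mean signal, and 14109 genes with a mean signal of at least 100 were tested. Arrays were scaled to a trimmed mean of 500, which left the values as they were, and log2(signal + 32) was taken. All differences are on this scale, which understates the change of genes with low signals.

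Tumours and cerebellum were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with two-sided p-values adjusted by Benjamini-Hochberg over all genes tested and a threshold of 0.05. The error given after ± is the standard error of the difference in this fit. With 1 cerebellum array the residual spread comes from the 4 tumours, and the prior added 5.02 degrees of freedom. Genes at least 2-fold from the cerebellum in each tumour were also counted, which needs no estimate of spread.

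For the comparison, 26 gene lists with 488 entries were written before the data were examined, as was the rule for naming genes; 439 entries had a named probe set, and 25 lists had at least 5 measured genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated for each list, adjusted over the 25 lists. With an estimated correlation camera also uses the few residual degrees of freedom of the arrays, so the settings differ in more than the correlation. "Adjusted over the list alone" means Benjamini-Hochberg within the list. Each list's median was also ranked among 10000 random lists of the same size matched on mean signal. The named genes included Cxcr6, Cxcl16, Gli1, Ptch1, Hhip, Sfrp1, Smo, Mycn, Ccnd1, Ccnd2 and Atoh1, the 10 genes furthest in each direction among those called with all 4 tumours on 1 side, up to 4 members of each list with the largest absolute differences, and the 10 genes with the largest SD among tumours, passing over symbols that are clone or prediction names. The further list members B2m, Barhl1, Casq2, Dcx, Gas1, Lhx5, Mdm2, Mki67, Neurod1, Plk2, S100b and Tyrobp were named after their values were seen.

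The procedure was tested on data simulated for these 14109 genes with 4 arrays against 1, in 20 runs with 200 genes changed. It called 7.5% of genes changed by 1 on the log2 scale, 59.3% of those changed by 2, 72% by 3 and 75.5% by 4, with 8.05 false calls on average. With no gene changed it called 0.5 genes and 0.15 lists on average, and a list shifted by design was called in 20 of 20 runs. Genes were simulated independently, whereas the correlation estimated in the data was 0.495 for DNA replication and 0.594 for mitosis genes. The simulated rates for lists therefore do not carry over to lists whose genes vary together. The simulation gives the cerebellum the spread of the tumours, which the data cannot check.

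Alternatives were other scalings (none, quantile, equal medians), other treatments of low signals (constants of 8 and 128, or a floor of 50), other filters (none, or a mean of at least 200), other choices of probe set (the mean of all, or without those whose names end in x_at or s_at), eBayes without a trend, other thresholds, the hmk arrays alone, and each tumour left out in turn. The ken tumours with the cerebellum were added after the prefixes were seen to differ.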

Results

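Gene expression was measured on 5 arrays from mice: 4 medulloblastomas, a tumour of the cerebellum, and 1 sample of P5 cerebellum, where P5 is read as postnatal day 5. The cerebellum has no replicate, so every comparison of tumours with cerebellum below rests on a single normal array, which limits the precision. No age is given for the tumours, so a difference from the P5 cerebellum cannot be told apart from a difference in age. The series title concerns tumours of mice mutant for the chemokine receptor Cxcr6 and their response to an inhibitor of Smoothened, the receptor component that turns on Hedgehog signalling. Genotype and treatment are not given for the single arrays, so neither was compared, and the comparison made here is of the tumours with the P5 cerebellum. The median signal over all probe sets was between 191 and 213 in the tumours and was 232 in the cerebellum. The ratio of 3' to 5' signal, a sign of RNA integrity, was highest in medulloblastoma 1. It was 1.45 for actin and 0.946 for Gapdh there, against 1.21 to 1.35 and 0.731 to 0.824 on the other arrays. Being highest is a rank among these 5 arrays and no finding of degraded RNA. Whether the ratios bear on any result below was not tested. Across 14109 genes, the tumours correlated with each other at r between 0.881 and 0.936. Their r with the cerebellum was 0.880 for medulloblastoma 1, 0.871 for medulloblastoma 2, 0.837 for medulloblastoma 3 and 0.832 for medulloblastoma 4. These correlations are across genes, which are not independent replicates.

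Among the 10 genes furthest above the cerebellum were the cerebellar granule neuron gene Gabra6, the transcription factor genes Olig3 and Lhx2, and Gpnmb. Atoh1, which marks granule neuron precursors, was also called, with signals of 4178, 7341, 9505 and 7872 in medulloblastomas 1 to 4 against 963 in the cerebellum, a log2 difference of 2.81 ± 0.40 (SE; limma, adjusted p = 0.0336). Olig3 was higher by 3.79 ± 0.39 and Lhx2 by 3.90 ± 0.38 on the log2 scale. Gabra6, a GABA-A receptor subunit of mature granule neurons, was higher by 3.99 ± 0.63, from 164 in the cerebellum to between 1664 and 6856 in the tumours. Gpnmb, a glycoprotein of macrophages and other cells, was higher by 4.16 ± 0.35, and Wfdc17 by 3.58 ± 0.53. A second, dim probe set of Gpnmb showed no difference (40.1, 51.7, 61.4 and 25.9 against 42.3), and with both averaged the Gpnmb difference was 2.09 and not called. The largest difference was that of Lyz1, at 6.03 ± 0.43 (adjusted p = 0.00906). The probe set used for Lyz1 is of a kind that can also bind transcripts of related genes, and Lyz2, its close relative, was higher by 3.35 ± 0.40. With such probe sets left out, the Lyz1 difference was -0.55, so the level of Lyz1 itself is uncertain. The remaining genes among the 10 largest increases were Itih3 (4.47 ± 0.61), Fam107a (4.34 ± 0.51), Fosl2 (4.11 ± 0.35) and the myelin gene Mobp (3.71 ± 0.58). For Mobp, 1 of the 3 other bright probe sets had the opposite sign. A second probe set of Fosl2 showed no such difference (319, 386, 316 and 278 against 310), and with all probe sets averaged the Fosl2 difference was 2.08, and that of Mobp 1.35, neither of them called. The cerebellum signals of Fosl2, Lhx2 and Wfdc17 were 22.7, 13.8 and 19.9, below the constant of 32 added before taking logs, so their differences depend on that constant.

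Genes encoding a retinoic acid enzyme, the apelin receptor, a matrix protein and an astrocyte enzyme were among the 10 furthest below the cerebellum. Cyp26b1, an enzyme that degrades retinoic acid, fell by 4.46 ± 0.51 on the log2 scale, from 1994 in the cerebellum to between 47.8 and 81.5 in the tumours (limma, adjusted p = 0.0240). Aplnr, the apelin receptor, fell by 4.07 ± 0.47. Tnc, which encodes the matrix protein tenascin C, fell by 3.52 ± 0.46. The folate enzyme gene Aldh1l1, an astrocyte marker, fell by 2.64 ± 0.28, from 4062 to between 567 and 770. Id3, a target of BMP signalling, fell by 2.47 ± 0.26. The netrin receptor gene Unc5c fell by 2.46 ± 0.37, and Gucy1a1, a subunit of the nitric oxide receptor, fell by 2.83 ± 0.36. Ly6h and Mid1 each fell by 3.06 (SE 0.36 and 0.43), and Acot1 fell by 2.85 ± 0.39. The 2 other, dim probe sets of Mid1 differed by -0.59 and 0.57, and with all 3 averaged the Mid1 difference was -1.03 and not called.

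**Figure D1:**
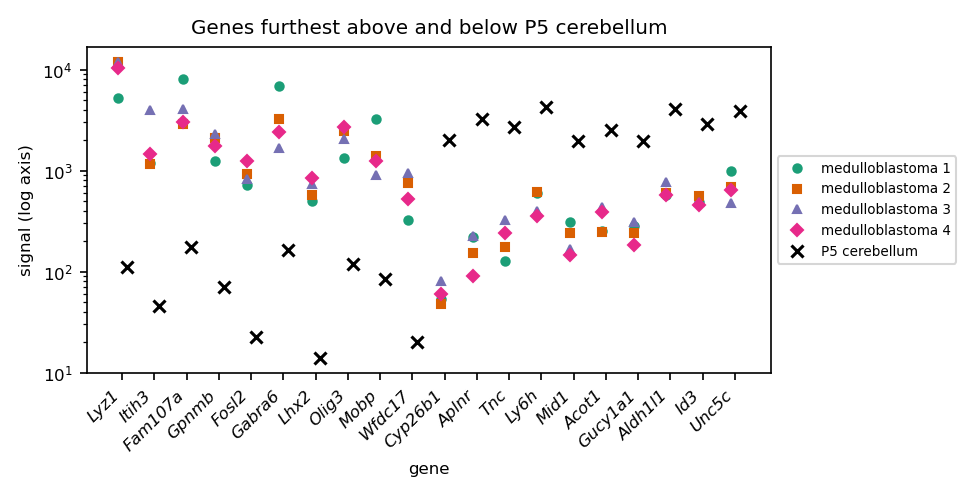
Signals on a log axis of the 10 genes with the largest increase and the 10 with the largest decrease among genes past the threshold; coloured points are the 4 medulloblastomas and crosses the single P5 cerebellum. For each gene all 4 tumours lie on the same side of the cerebellum, as with Cyp26b1, at 1994 in the cerebellum and at most 81.5 in a tumour.

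In all, 44 genes were higher and 25 lower in the medulloblastomas at a Benjamini-Hochberg adjusted p under 0.05 (limma), and at an unadjusted p under 0.05 the numbers were 1089 and 1050. All 69 called genes lay at least 2-fold from the cerebellum in each of the 4 tumours, as did 284 genes on the higher and 371 on the lower side without a test. The spread comes from the tumours alone, with 3 residual degrees of freedom, and the cerebellum array is assumed to vary like them. An exact permutation of 4 arrays against 1 cannot give a p under 0.2, and the submitters describe the replicates as too few for statistics. The number of calls depended strongly on single arrays: it was 448 higher and 383 lower without medulloblastoma 1, the array with the highest 3' to 5' ratios, 2 and 0 without medulloblastoma 2, 10 and 6 without medulloblastoma 3, and 0 and 0 without medulloblastoma 4, where 806 and 896 genes had an unadjusted p under 0.05. It was 0 and 0 when limma's variance was not allowed to vary with signal (908 and 1099 at an unadjusted p under 0.05). Sample titles start with ken for medulloblastomas 1 and 2 and with hmk for the other 3 arrays. A fit with the tumours of 1 prefix takes its spread from a single pair of tumours, and the cerebellum is assumed to vary like that pair. Its counts therefore do not measure the strength of the difference. Within the hmk arrays 837 genes were higher and 841 lower, whereas the ken arrays hold no cerebellum; set against the hmk cerebellum, they gave 21 and 16. With the arrays scaled to equal medians, which moves the median difference of all genes from -0.07 to 0.12, the calls were 78 higher and 20 lower.

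Cxcr6, the gene named in the series title, had low signals. Its 2 probe sets read 37.4, 6.65, 87.3 and 6.41, and 14.5, 82.1, 123.9 and 51.1, in medulloblastomas 1 to 4, and 6.01 and 34.9 in the cerebellum. The gene was left out of the tests for low signal, and the part of the gene that the probes cover was not known here. Its ligand gene Cxcl16 had signals of 386, 457, 327 and 396 in the tumours and 379 in the cerebellum, a log2 difference of 0.03 ± 0.32. A second, dimmer probe set of Cxcl16 differed, at 75.5, 81.1, 242 and 386 against 9.03 (2.24), and with both averaged the Cxcl16 difference was 1.14 and not called.

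Genes induced by Hedgehog signalling were on the whole higher in the tumours: the median log2 difference of 17 measured targets was 0.79, and 11 of them were above the cerebellum in all 4 tumours. The list passed limma's camera test with a preset correlation (adjusted p = 0.00196), but not with an estimated one (adjusted p = 0.443 with an estimated correlation). Only the cell-cycle kinase gene Cdk6 passed over all genes tested, with a log2 difference of 2.73 ± 0.39 (adjusted p = 0.0341). Adjusted over the list alone, 5 targets were higher and 2 lower. The cyclin gene Ccnd1 read 23239, 8391, 9962 and 8033 in the tumours against 2407 in the cerebellum (2.20 ± 0.52, adjusted p = 0.125 over all genes). Gli1, the transcription factor commonly used as a readout of the pathway, read 2012, 2962, 1872 and 2436 against 1510, a difference of 0.59 ± 0.29 with an adjusted p of 0.381. Hhip, which binds Hedgehog ligands, read 218, 178, 640 and 370 against 121 (1.18 ± 0.62), with 0.14 to 1.20 at its 3 other probe sets. Sfrp1 read 9661, 9394, 3172 and 6232 against 2894 (1.16 ± 0.54), and Ccnd2 read 11018, 18841, 13775 and 20281 against 8977 (0.79 ± 0.33). Mycn read 4900, 6032, 6521 and 6082 against 2895, a difference of 1.01 ± 0.23 with an adjusted p of 0.115, which became -0.07 when all probe sets of the gene were averaged. Of its 2 other probe sets, the brighter was also higher (0.54). The dimmest was lower (-1.75), at 346, 55.9, 49.2 and 30.2 against 351. Igf2 and the neural tube gene Nkx2-2 were lower over the list alone, by log2 differences of -1.84 and -1.50.

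Ptch1, the Hedgehog receptor and a target of the pathway, differed between the tumours: its signal was 692 and 451 in medulloblastomas 1 and 2, 2811 and 2352 in medulloblastomas 3 and 4, and 2538 in the cerebellum. The difference over the 4 tumours was -1.05 ± 0.89 (adjusted p = 0.598), and within the hmk arrays it was 0.02. Smo itself read 1766, 2297, 1925 and 2104 against 1596 (0.33 ± 0.24). Other components of the pathway were not called as a list (median -0.37 over 16 genes, camera adjusted p = 0.280), with none of them past the threshold over all genes. Their medians were -0.19, -0.31, -0.44 and -0.37 in medulloblastomas 1 to 4. Over that list alone Gas1 was higher (1.27 ± 0.31) and Scube2 lower (-3.38 ± 0.85).

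**Figure D2:**
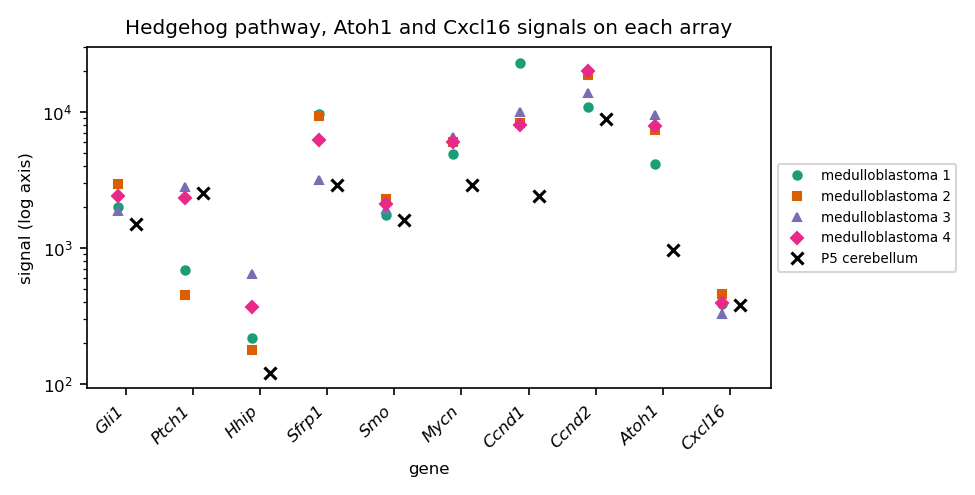
Signals on a log axis of Hedgehog pathway genes, Atoh1 and Cxcl16; coloured points are the 4 medulloblastomas and crosses the P5 cerebellum. Ccnd1 and Atoh1 lie above the cerebellum in all 4 tumours, and Ptch1 separates medulloblastomas 1 and 2 (692 and 451) from medulloblastomas 3 and 4 (2811 and 2352).

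Genes of DNA replication and of mitosis were modestly higher in all 4 tumours. The median log2 difference was 0.73 over 29 replication genes, 24 of them above the cerebellum in every tumour, and 0.59 over 27 mitosis genes, 22 of them above in every tumour. Both lists passed camera with the preset correlation (adjusted p = 6.97e-10 and 6.41e-09) and neither with an estimated one (adjusted p = 0.454 and 0.467 with an estimated correlation). No member passed over all genes tested; adjusted over the list alone, 9 replication genes were higher, with Mcm4 (1.32 ± 0.29), Pola1 (1.17 ± 0.35) and Mcm2 (1.16 ± 0.31) the furthest, and 3 mitosis genes, Anln (1.33 ± 0.27), Kif11 (1.18 ± 0.31) and the proliferation marker Mki67 (0.85 ± 0.21). A second probe set of Mcm2 showed no increase (2912, 2921, 3856 and 2432 against 3203), and the mean of all its probe sets was 0.53 higher. Targets of p53 and cell-cycle inhibitors, taken as 1 list of 21 genes, had a median of 0.61 (camera adjusted p = 0.000995; adjusted p = 0.487 with an estimated correlation). Over that list alone, 5 genes were higher and 2 lower: Eda2r (1.74 ± 0.38), Pmaip1 (2.05 ± 0.57) and Mdm2 (0.92 ± 0.26) were among the first, and Cdkn1c (-1.87 ± 0.47) and Plk2 (-1.70 ± 0.39) were the others. Ribosomal protein genes had a median of 0.49, with 14 of 15 above the cerebellum in every tumour and none called singly. Their list passed camera (adjusted p = 3.99e-06; adjusted p = 0.443 with an estimated correlation), but not after quantile normalization, where the median was 0.17 (adjusted p = 0.0559).

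Genes of the granule neuron lineage did not move together. The precursor list had a median of 0.03 over 20 genes (camera adjusted p = 0.514): over the list alone Atoh1, the chemokine receptor gene Cxcr4 (1.44 ± 0.38), Mycn and Barhl1 (0.97 ± 0.24) were higher, and Eya1 (-1.45 ± 0.43), Pax6 (-1.02 ± 0.34), Dcx (-0.95 ± 0.23) and Neurod1 (-0.81 ± 0.23) lower. Mature granule neuron genes had a median of 0.01 and a mean of 0.58 over 14 genes (camera adjusted p = 0.303). Their medians per tumour were 1.17, 0.13, -0.60 and -0.24 in medulloblastomas 1 to 4, highest on the array with the highest 3' to 5' ratios. Besides Gabra6, Cbln3 was higher over the list alone (3.11 ± 0.69), at 8384 in medulloblastoma 1 and between 1692 and 3888 in the others against 382. The list of Purkinje cell genes had a median of -1.18 over 17 genes and missed the threshold (camera adjusted p = 0.0544; adjusted p = 0.651 with an estimated correlation), but passed it in 8 of 18 alternatives. Over that list alone, 5 genes were lower, led by the neurofilament genes Nefl (-3.32 ± 0.68) and Nefm (-2.66 ± 0.66), and Pvalb (2.38 ± 0.58) and Casq2 (1.73 ± 0.43) were higher. Genes of inhibitory interneurons were lower as a list, with a median of -1.38 over 10 genes and 8 of them below the cerebellum in every tumour (camera adjusted p = 0.000191; adjusted p = 0.443 with an estimated correlation). The 4 that passed over the list alone were Sst (-2.33 ± 0.55), Ptf1a (-2.34 ± 0.70), Gjd2 (-1.84 ± 0.46) and Lhx5 (-1.53 ± 0.43), and none passed over all genes. Synapse genes had a median of -0.50 over 20 genes (camera adjusted p = 0.121), with a median of 0.28 in medulloblastoma 1 and negative medians in the other 3.

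Genes of microglia and macrophages were higher in the tumours, with a median log2 difference of 1.37 over 19 genes and medians per tumour of 1.05, 1.35, 1.48 and 1.33. The 4 members Lyz2, the protease gene Ctss (2.37 ± 0.23), the complement gene C1qa (1.95 ± 0.25) and Tyrobp (1.44 ± 0.23) passed over all genes tested, and none was called lower. Adjusted over the list alone, 10 were higher. In every tumour 15 of the 19 lay above the cerebellum and 2 below it. The list passed camera with the preset correlation (adjusted p = 2.03e-09; adjusted p = 0.153 with an estimated correlation). Lymphocyte genes had a median of -0.44 over 6 genes with none called (camera adjusted p = 0.397), and among the erythroid genes 2 could be measured, Bpgm (0.35 ± 0.28) and Slc4a1 (-0.34 ± 0.65). Interferon-response and MHC class I genes had a median of 0.50 over 17 genes (camera adjusted p = 0.0366; adjusted p = 0.651 with an estimated correlation), with Ifit2 (2.41 ± 0.49) and B2m (1.36 ± 0.29) higher over the list alone. This shift rested on medulloblastoma 1, the array with the highest 3' to 5' ratios, whose median was 1.17: without it the median was -0.01 and the list was not called (adjusted p = 0.156).

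Astrocyte, vessel and connective tissue genes were lower. The list of astrocytes and Bergmann glia, the radial glia of the cerebellum, had a median of -0.80 over 18 genes (camera adjusted p = 0.0272; adjusted p = 0.443 with an estimated correlation). Aldh1l1 and the water channel gene Aqp4 (-2.09 ± 0.27) passed over all genes; over the list alone 9 were lower, Gdf10 (-2.82 ± 0.62) and Fabp7 (-2.42 ± 0.59) among them, and 2 higher, including S100b (1.62 ± 0.35). Meningeal and fibroblast genes had a median of -1.15 over 18 genes, with Col3a1 (-2.40 ± 0.30) past the threshold over all genes and 10 lower over the list alone (camera adjusted p = 6.16e-06; adjusted p = 0.443 with an estimated correlation). Endothelial and pericyte genes had a median of -1.03 over 17 genes, 13 of them below the cerebellum in every tumour (camera adjusted p = 0.000306; adjusted p = 0.467 with an estimated correlation). None passed over all genes and 6 were lower over the list alone, including Pecam1 (-2.18 ± 0.58), Kdr (-1.90 ± 0.45) and Cdh5 (-1.71 ± 0.44). Oligodendrocyte lineage genes had a median of 0.02 over 15 genes (camera adjusted p = 0.608), with Mobp called over all genes at the probe set used and, over the list alone, Mal (1.95 ± 0.43; 0.27 at a second probe set) higher and Gpr17 (-2.03 ± 0.50) lower.

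Of the 11 lists that passed camera with the preset correlation, 10 also passed within the hmk arrays, the exception being the interferon list with a median of 0.06 (adjusted p = 0.0944), and 11 passed with the ken tumours set against the cerebellum. Both sets of tumours were part of the fit that chose these lists, and both were set against the same cerebellum array. Their passes were thus largely fixed by the selection and are no independent check. None of the 11 passed with an estimated correlation. Those estimates ran from -0.0077 for the microglia and macrophage list to 0.594 for the mitosis list. The microglia estimate lies below the preset 0.01, so a higher correlation is not why that list lost its call. Among 10000 random lists of equal size and similar signal, the medians of the 7 raised lists lay at percentiles between 98.45 and 100 and those of the 4 lowered lists at 0, as a description of these arrays. The Purkinje and synapse lists, not called, also lay at 0. The other lists missed the threshold in this fit, although some of them passed it in alternatives. Notch pathway genes had a median of -0.33 over 15 genes (camera adjusted p = 0.0540; called in 6 of 18 alternatives), with Hes5 (-2.33 ± 0.51), Notch3 (-1.76 ± 0.36) and Dll1 (-1.46 ± 0.37) lower over the list alone. Chemokine and receptor genes had a median of -0.36 over 12 genes (camera adjusted p = 0.514), which was 0.04 with arrays scaled to equal medians. Within it, over the list alone, Cxcl12 (-1.77 ± 0.32) and Ccl27a (-1.35 ± 0.39) were lower and Cxcr4 higher. Wnt targets had a median of -0.53 (camera adjusted p = 0.280), hypoxia and glycolysis genes -0.23 (camera adjusted p = 0.514), immediate early genes 0.18 (camera adjusted p = 0.164) and choroid plexus genes -0.47 (camera adjusted p = 0.608). In the hypoxia and glycolysis list, over the list alone, the hexokinase gene Hk2 was higher (2.73 ± 0.49) and Pfkp lower (-1.83 ± 0.46).

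**Figure D3:**
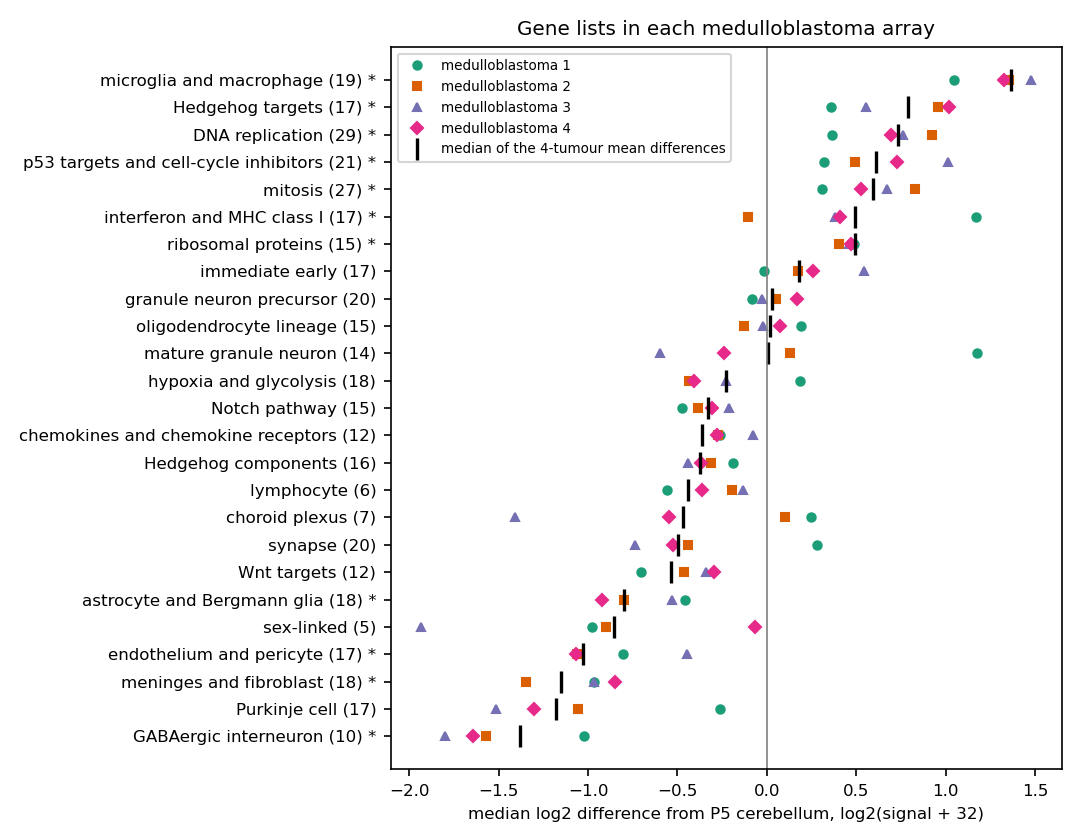
Median log2 difference from the P5 cerebellum of each gene list; coloured points give each medulloblastoma, black bars the median over genes of the mean of 4 tumours, numbers in brackets the measured genes and asterisks the lists past the preset-correlation camera threshold. The microglia and macrophage list lies between 1.05 and 1.48 in the 4 tumours, and the mature granule neuron list between -0.60 and 1.17.

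The tumours also differed from one another. The SD among the 4 tumours had a median of 0.31 on the log2 scale over all genes, and it was 3.40 for Prm1, which encodes a sperm chromatin protein and read 30.5, 6.33, 2580 and 3117 in medulloblastomas 1 to 4 against 36.2 in the cerebellum. Xist, the RNA of the inactive X chromosome, read 28827, 16680, 2961 and 163 against 4995, and the Y-linked gene Eif2s3y read 19.3, 46.0, 2.70 and 282 against 506. The list of sex-linked genes, with 5 measured members, was not called (camera adjusted p = 0.280). It joins Xist with Y-linked genes, whereas camera looks for a shared direction, so this says nothing about differences of sex. Dazl, a germ cell gene, read 3273 in medulloblastoma 4 and at most 10.02 in the other tumours. Tnnc2, a muscle troponin gene, read 1790 in medulloblastoma 1 and at most 24.2 in the others. Gdpd3 read 4063 and 1541 in medulloblastomas 1 and 2 and 49.2 and 74.1 in medulloblastomas 3 and 4. The homeobox gene Otx1 read 36.3, 479, 2067 and 2125 in that order, and the growth factor gene Mdk 461, 2334, 10189 and 10444. Foxd1 read 1137, 185, 4.20 and 13.0. Tecta was low in medulloblastoma 3 (13.1 against 1149 to 1635 in the others), and Mndal in medulloblastoma 4 (9.74 against 701 to 1932).

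**Figure D4:**
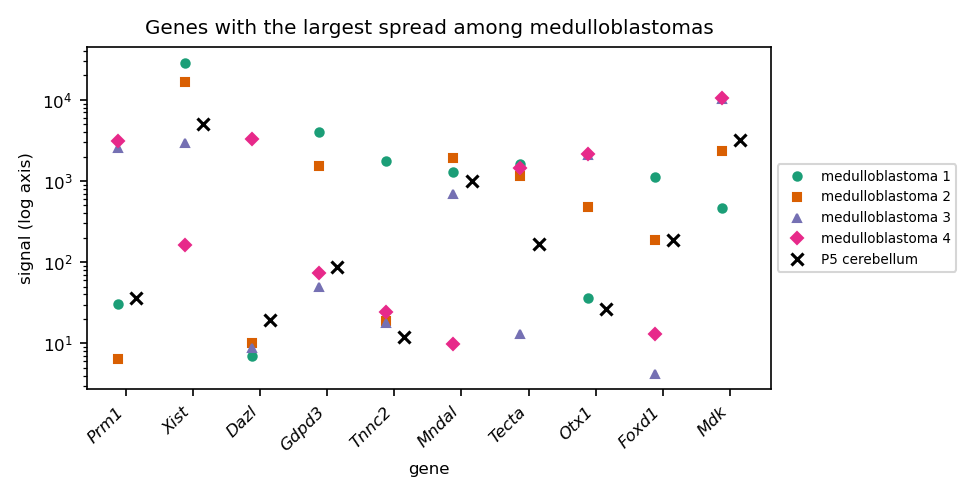
Signals on a log axis of the 10 genes with the largest SD among the 4 medulloblastomas; coloured points are the tumours and crosses the P5 cerebellum. Prm1 lies at 2580 and 3117 in medulloblastomas 3 and 4 and at 30.5 and 6.33 in medulloblastomas 1 and 2, and Dazl stands at 3273 in medulloblastoma 4 alone.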

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

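All tests of explanations in this part were chosen after the result was seen. Among 135 named genes and 25 list medians, 12 genes and 1 list had 1 tumour far from the other 3, with a gap to the nearest of them that took most of the range of log2 values; chance flags about 1 in 20 groups. That rate does not apply to the 10 genes named for their spread among tumours, which gave 3 of the 12 (Dazl, Tnnc2 and Tecta); the other 125 gave 9. Medulloblastoma 1 was the array standing apart for 9 of these genes, at the probe set used for each. A second probe set did not show it for Adm (96.3, 105, 214 and 123 in medulloblastomas 1 to 4). The same held for Jag2 (159, 114, 120 and 171) and Hes5 (127, 309, 141 and 10.1). Fabp7, Scube2 and Tnnc2 had no other named probe set. Medulloblastoma 1 was still the extreme at a second probe set of Ifi27 (1290 against 439, 598 and 620) and of Lyz1 (743 against 4656, 6110 and 3384). It was so too for Racgap1 (1378 against 2134, 2365 and 2249), but the gap as a share of the range was not computed at these probe sets of medulloblastoma 1. This array also had the highest ratio of 3' to 5' signal, for actin (1.45 against 1.21 to 1.35 on the others) and Gapdh (0.946 against 0.731 to 0.824); whether that bears on these genes was not tested. Their gap as a share of the range, and the signals of medulloblastomas 1 to 4, were as follows. Adm had a share of 0.908, with 13.8 in medulloblastoma 1 against 106, 104 and 119. Fabp7 had 0.896, with 2200 against 6505, 7371 and 6917, and Hes5 0.880, with 100.4 against 236, 264 and 260. Racgap1 had 0.887, with 1880 against 3458, 3701 and 3428, and Lyz1 0.837, with 5247 against 11772, 11915 and 10427. On the high side, Ifi27 had 0.848, with 2474 against 413, 352 and 294, Jag2 had 0.831, with 313 against 134, 139 and 156, and Scube2 had 0.907, with 83.6 against 14.2, 18.3 and 18.0. The share was 0.968 for Tnnc2, also high in medulloblastoma 1. In other tumours, Col1a1 was low in medulloblastoma 2 with a share of 0.873 (85.3 against 317, 339 and 377). Dazl was high in medulloblastoma 4 with 0.983, at both of its probe sets (3273 and 1266). Tecta was low in medulloblastoma 3 with 0.905. The median of the chemokine list was highest in medulloblastoma 3, with a share of 0.907 (-0.08 against -0.26, -0.27 and -0.28).

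Mature granule neuron genes were highest in medulloblastoma 1, for 13 of 14 measured genes. The arrays already had equal trimmed means, so a brighter array as a whole, which would move all genes alike, could not show here. The median log2 difference of medulloblastoma 1 from the other tumours' mean was 1.57 higher for these genes (SD 0.55) than for all genes. That gap is no test of brightness, since the list was looked at for being highest there. In the same tumour, 23 of 29 DNA replication and 19 of 27 mitosis genes were lowest. Normal cerebellum like the P5 sample, taken along with the tumour, is argued against for 8 of the 14 genes, since their excess in medulloblastoma 1 over the highest other tumour was larger than their whole P5 signal (Gabra6 read 6856, at most 3252 in another tumour and 164 at P5). More mature cerebellum may have contributed and cannot be told apart, because no array of it was used here: genes of Purkinje cells, which do not come from granule precursors, were also highest in medulloblastoma 1 in 76.5% of 17 cases, against 30.9% of all genes, with log2 differences from P5 between -2.05 (Nefl, 1277 against 5405) and 3.43 (Pvalb, 7201 against 638); of 18 genes of astrocytes and Bergmann glia, 8 were highest and 4 lowest there. Of 10 genes of inhibitory interneurons, 7 were highest and 0 lowest in medulloblastoma 1, and of 20 synapse genes 14 were highest and 2 lowest. The order was not limited to neurons. In medulloblastoma 1, 94.1% of interferon and MHC class I genes and 72.2% of hypoxia and glycolysis genes were highest as well. No biological explanation other than normal cerebellum taken along with the tumour was tested.

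Setting each of the 5 arrays alone against the other 4, the cerebellum was the 1 array that gave as many as 69 called genes, and the highest number for another array was 0 (limma; between 138 and 869 genes at an unadjusted p under 0.05). With 5 choices a share under 0.05 cannot be reached. Without a test, 655 genes lay at least 2-fold from the cerebellum in all other arrays, against 345, 88, 227 and 191 for medulloblastomas 1 to 4. For a tumour this count also needs the cerebellum on the same side as the other tumours, so the counts are not like for like.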

How the results depend on the processing

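The alternatives were fixed before the data were examined, except the ken tumours with the cerebellum, chosen after seeing the data. No paired analysis was possible because the cerebellum has 1 sample. Leaving the values unscaled moved nothing, as the arrays already had equal trimmed means. Detection calls were not used, so what signal over background limits is unknown for genes near the floor. Of the 69 genes called, 69 kept their direction under each alternative except the removal of x_at and s_at probe sets, where 68 did. With the same probe set and cerebellum array this was largely fixed by the selection, because all 69 lay at least 2-fold from the cerebellum in each tumour. It is therefore no sign of robustness there. The alternatives that changed the probe set were the main check of direction: 69 kept theirs with the mean of all probe sets and 68 without x_at and s_at probe sets. Of 2265 values of 135 named genes under alternatives, 1995 stayed on the same side of the threshold in the same direction, 136 lost a call, 108 gained one and 26 changed sign. Most named genes were not called in the main fit, so the 1995 include many values that stayed uncalled. The 136 lost calls all came from the minority that were called. Each of those genes lost its call in 3 (as Ctss) to 8 (as Gabra6) of 17 alternatives. Where a cause is not given below, the cause was not tested.

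The counts of called genes (44 higher, 25 lower) became 78 higher and 20 lower with equal medians (79.6% higher against 63.8%), 40 and 45 with the larger added constant (47.1% higher), 14 and 12 without a filter, 11 and 5 with the mean of all probe sets, and 0 and 0 without a trend, where the smallest adjusted p was 0.0814. They were 837 and 841 in the hmk arrays, 21 and 16 with the ken tumours (26 of the 69 genes called again) and 1 and 0 at an adjusted p of 0.01. Leaving out 1 tumour gave 0 to 448 higher and 0 to 383 lower, highest without medulloblastoma 1. The untested counts of genes at least 2-fold higher in each of the 4 medulloblastomas (284) and genes at least 2-fold lower in each of the 4 medulloblastomas (371) became 129 and 229 with the larger added constant, 761 and 1069 in the hmk arrays, 429 and 622 with the ken tumours, 755 and 1075 at 1.5-fold and 82 and 105 at 3-fold. Fewer tumours, or a lower fold, make this count larger by construction. The lower count was 234 with equal medians and 558 without a filter. Without 1 tumour they ran from 320 to 525 and from 439 to 651. The counts of called genes with the hmk or ken tumours took their spread from a single pair of tumours. They therefore do not measure the strength of the difference.

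With an estimated correlation no list was called, at unchanged medians: Hedgehog targets 0.79 (adjusted p = 0.443), interneurons -1.38 (0.443), astrocytes -0.80 (0.443), microglia 1.37 (0.153), endothelium -1.03 (0.467), meninges -1.15 (0.443), DNA replication 0.73 (0.454), mitosis 0.59 (0.467), p53 targets 0.61 (0.487), interferon 0.50 (0.651) and ribosomal proteins 0.49 (0.443). The astrocyte list also lost its call with the mean of all probe sets (-0.81) and without a trend (-0.80). The interferon list lost its call with equal medians (0.64), with the mean of all probe sets (0.33), without x_at and s_at probe sets (0.12), without a trend (0.50) and in the hmk arrays (0.057), and ran from -0.014 without medulloblastoma 1 to 0.76 without medulloblastoma 3. Ribosomal proteins lost theirs with quantile normalization (0.17).

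Lists not called gained a call as follows: Purkinje cells in 8 of 18 alternatives (adjusted p down to 0.00010, at -1.58 in the hmk arrays), Notch in 6, synapse in 3, mature granule neurons in 2 (the ken tumours, 0.54, and without medulloblastoma 3, 0.21) and immediate early genes in 1 (the hmk arrays, 0.53). Lists not called changed sign as follows: granule precursors with quantile normalization (-0.069) and the ken tumours (-0.062), and from -0.050 to 0.11 without 1 tumour; mature granule neurons in the hmk arrays (-0.42), and from -0.24 to 0.21 without 1 tumour; oligodendrocytes at a mean signal of 200 (-0.034) and with the ken tumours (-0.057), and from -0.080 to 0.0018 without 1 tumour; lymphocytes without a filter (0.25); choroid plexus with the ken tumours (0.18); chemokines with equal medians (0.037).

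Genes changed sign as follows. Without x_at and s_at probe sets the differences were 1.67 for Adm, 1.27 for Cd8a and -0.55 for Lyz1. With the mean of all probe sets they were -0.10 for Il2rb, -0.068 for Mycn, -0.017 for Sostdc1 and 0.41 for Xist. In the hmk arrays they were -0.068 for Cxcl16, -0.37 for Gdpd3, 0.019 for Ptch1 and 0.022 for Slc4a1. With the ken tumours they were -0.34 for Dazl, 1.19 for Foxd1, -1.60 for Mdk, 0.63 for Mndal, 0.65 for Otx2, -0.48 for Prm1 and 2.13 for Xist. With quantile normalization Mdk was at -0.088. Without 1 tumour, Cxcl16 ran from -0.037 to 0.11, Dazl from -0.33 to 1.80, Foxd1 from -1.64 to 0.032, Mdk from -0.51 to 0.96, Mndal from -1.60 to 0.26 and Xist from -1.23 to 1.17.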

Other observations

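All tests in this part were chosen after the result was seen, as were the genes named by them. Across genes, medulloblastoma 2 (ken) correlated slightly more with medulloblastomas 3 and 4 (hmk; r = 0.932 and 0.930) than with medulloblastoma 1 (ken; r = 0.924). In a limma fit with the cerebellum as its own group and 2 residual degrees of freedom, 3 genes were higher in medulloblastomas 3 and 4 (hmk) than in medulloblastomas 1 and 2 (ken) and 3 lower at an adjusted p under 0.05. The higher ones were Prm1 by 5.87 ± 0.40 on the log2 scale (adjusted p = 0.00354), the endosomal GTPase gene Rab5c by 2.28 ± 0.25 (adjusted p = 0.0376) and Ptch1 by 2.14 ± 0.25 (adjusted p = 0.0464). The lower ones were Erdr1, which fell by 1.95 ± 0.17 (adjusted p = 0.0111), the homeobox gene Otx2, which fell by 3.27 ± 0.30 (adjusted p = 0.0134), and Gdpd3, which fell by 4.77 ± 0.46 (adjusted p = 0.0145). Otx2 read 1608 and 1111 in medulloblastomas 1 and 2, 95.3 and 126 in medulloblastomas 3 and 4, and 843 in the cerebellum. The split by prefix was the 1 of 3 splits of the tumours into pairs with as many as 6 called genes, and the highest number in another split was 0 (235 and 272 genes at an unadjusted p under 0.05, against 1740). In the other splits each pair mixes the prefixes, so a prefix difference widens their spread and makes calls less likely. With 3 splits a share under 0.05 cannot be reached, and the labels do not say what the prefix stands for.

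Prm1 was high in medulloblastomas 3 and 4. One faulty probe set is argued against by its 3 probe sets, 3 of which were higher in both tumours than on each other array, although all are of the kind that can bind related transcripts. RNA of spermatids is argued against by 26 other spermatid genes, some of them looked at before the list was written, whose median log2 difference between the pairs was 0.25 (range -1.28 to 1.74); Prm2 and Tnp1, among the most abundant in spermatids, read at most 130.4 and 122.8 in these tumours. A candidate explanation is an engineered sequence that carries part of Prm1, whose end has been used in constructs, in the mice of these tumours. The difference of 5.87 does not bear on it, because no genotype is given, and it cannot be told apart from other differences between the pairs.

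Ptch1 was low in medulloblastomas 1 and 2. One faulty probe set is argued against, since at 3 of 3 probe sets both tumours were lower than every other array. A smaller share of Hedgehog-responding cells would lower the other targets by about as much, but the median log2 difference of 16 other targets between the pairs was 0.20 (SD 0.56, highest 1.18), below the 2.14 of Ptch1. A change at the Ptch1 locus in these tumours may account for the low signal. Such a change cannot be told apart from other differences between the pairs, because the labels give no genotype. The 2.14 does not bear on it, being the difference to be explained.

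Xist and Y-linked genes were both seen in the cerebellum, with Xist at 4995, Eif2s3y at 506 and Kdm5d at 348; the labels say neither its sex nor whether animals were pooled. Medulloblastoma 4 read 163 for Xist and 282 for Eif2s3y, and medulloblastoma 1 read 28827 and 19.3.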
